A study of Brassica napus with 18 samples.

How the data were processed

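Poly(A)-selected RNA-seq libraries were made from shoot apices of field-grown oilseed rape (Brassica napus), an allotetraploid with an A and a C subgenome and 19 chromosomes. The labels name 6 accessions with 3 libraries each, 18 libraries in all. Per the labels' protocols, R5044, R5159 and R5161 carry haplotype 1 of BnaC3.LFY, and R4168, R4210 and R4817 carry haplotype 2. The labels do not say whether the 3 libraries of an accession came from separate plants or plots, so p-values that rest on the spread between libraries measure only the spread between these samples, which may be technical.

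The authors deposited 1 table of raw counts per gene model, as whole numbers that were not normalized. HISAT2 2.2.1 and featureCounts are named in the submitters' processing notes, without their settings or order. The genome build, the annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Because the A and C copies of a gene can be similar in sequence, counts of such pairs may share reads, and this holds for every gene and segment named. The table has 107233 gene models, of which 103213 lie on A or C chromosomes and 4020 on scaffolds, and 78688 had a count in at least 1 library. Columns were assigned to samples by their names, which equal the accession and replicate in the sample titles. No column of another series was present.

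The identifiers give the chromosome and a running gene number, and the table follows that number on every chromosome. Positions are therefore given as gene numbers along a chromosome, not as base pairs. None of the identifiers matched the RefSeq name table of the Da-Ae assembly, which holds 123214 entries (0 matches), so gene symbols were not used here. For this reason the LFY copies and the 12 gene lists fixed before the data were examined (flowering integrators, floral meristem identity, floral organ identity, shoot meristem, anther and pollen, photosynthesis, cold, clock, defence, gibberellin, cell cycle and heat shock) had 0 lists matched and were not analysed here.

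Total counts per library ranged from 21960992 to 41459636. In 9 against 9 libraries a gene with 0 counts in one haplotype was given a floor of 3 counts over the group, which covers counting error only. Library pairs were checked for duplicates: 0 columns were identical, and within accessions the lowest chi-square per degree of freedom between libraries was 5.34, far from sampling noise, so each library was kept as 1 sample.

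Comparisons were made in R 4.3.3 with edgeR 4.0.16. Fold changes are haplotype 1 over haplotype 2 on the log2 scale, and calls have a Benjamini-Hochberg adjusted p under 0.05. The accession-level test sums the 3 libraries of an accession and compares 3 against 3 accession sums with edgeR's quasi-likelihood test, TMM normalization and filterByExpr by haplotype, so that the accession is the replicate. The test of accession means fits 1 coefficient per accession to the 18 libraries (filterByExpr by accession) and contrasts the mean of the 3 haplotype 1 accessions with that of the 3 haplotype 2 accessions. It uses the spread between libraries of an accession and says nothing about other accessions of either haplotype. A gene was called separated when it passed that test and the 3 accession means of one haplotype (log2 CPM) all lay above the 3 of the other. An F test over the 6 accession coefficients and 15 pairwise contrasts from the same fit measured differences among accessions. Shares of calls per chromosome and subgenome were compared with Fisher's exact test, and calls with a called next neighbour in the same direction with 10000 shuffles over tested genes. Genes are not independent replicates in either of these. Segment totals were compared with two-sided exact permutation tests over the 6 accessions, in which 0.1 is the smallest p that 3 against 3 can give.

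After the data were seen, a scan along the chromosomes was added. The test-of-means log2 fold changes, centred on the median of all 57414 tested chromosome genes, were taken in windows of 100 gene numbers with at least 15 tested genes. A window was called shifted when its median differed from 0 by at least 0.5 and from 10000 random gene sets at an adjusted p under 0.05, and adjoining windows of one direction were joined into segments. Differences of single accessions were computed on log2(CPM + 0.1), a scale that understates the change of weakly expressed genes. The scan was made with Python (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1).

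The rule for named genes, fixed before the data were examined, takes all LFY copies, up to 4 members of each list, and the 10 genes with the highest and the 10 with the lowest log2 fold change past the threshold of the accession-level test with a mean of at least 1 CPM. Without gene names it allows at most 2 identifiers in each direction, and these are the 2 with the most extreme fold changes.

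The tests were run on simulated data first. With counts drawn for 57135 genes, the accession-level edgeR test recovered 3% of 2-fold and 93% of 8-fold changes, 100 genes each, with 6 false calls. The test of accession means, on 55727 genes, recovered 90% and 100%, with 9 false calls. The scan, on 57414 genes, recovered 20 of 20 shifted windows and called 1 other. The simulated counts had 1 spread for all genes and no accession effects, and the simulated scan values were independent between genes. The false calls therefore do not measure errors from accession differences or from correlated neighbours. With only 100 changed genes of each size, an adjusted p under 0.05 needs a smaller raw p than with the 7920 real accession-level calls. The recovered shares are thus not those of the 2 edgeR tests on the real counts. In the real counts, the other splits of the 6 accessions gave 14573 to 22899 calls in the test of accession means. Alternatives fixed in advance were another normalization (RLE), other filters on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), a minimum 2-fold change, libraries as replicates, a replicate block, and each library or accession left out. Thinning of all libraries to the smallest total, 21960992 counts, leaving out the genes of shifted segments, leaving out chromosomes A02 and C02 from the subgenome comparison and leaving out replicate 1 or 2 of R4817 were added after the data were seen. The last was chosen because these libraries had the lowest Spearman correlation of any pair within an accession, 0.904, where the other pairs had 0.953 to 0.986. The comparison of calls within 100 kb, also fixed in advance, was not run because no base-pair positions were used.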

Results

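The series compared the shoot apex transcriptomes of rapeseed accessions that carry either of 2 haplotypes of BnaC3.LFY, the copy on chromosome C03 of LEAFY, a transcription factor that specifies floral meristem identity. Per the series design, the question is what distinguishes accessions of the 2 haplotypes, 3 accessions each. The total count per library was 33372715 ± 3619287 in haplotype 1 and 26368783 ± 3318506 in haplotype 2 (mean and SD of 3 accession means; range over libraries 21960992 to 41459636), with an exact permutation p of 0.2. Each haplotype was represented by different accessions, so any difference in the genetic background of the accessions is part of every haplotype comparison.

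The shoot apices of the 6 accessions fell into 2 sets along the haplotypes. The first principal component of log2 CPM held 40.1% of the variance, with all 9 haplotype 1 libraries between -210.1 and -159.5 and all 9 haplotype 2 libraries between 144.7 and 266.2. Accessions of different haplotypes differed in 27166 ± 2455 genes per pair (mean and SD of 9 pairs), and accessions of 1 haplotype in 11155 ± 1053 (6 pairs). The fewest differences between haplotypes were 24241, for R5044 and R4168, and the most within a haplotype were 12152, for R5159 and R5161. The pair counts come from edgeR's quasi-likelihood test at an adjusted p under 0.05, and pairs share accessions. The excess of 16011 genes per pair was larger than under each of the other 9 splits of the 6 accessions, the highest of which gave -670 (exact one-sided p = 0.1, the smallest that 10 splits can give). Of the sum of squares of log2 CPM, 39.2% lay between haplotypes, 45.1% between accessions of a haplotype and 15.6% between libraries of an accession. At least 1 accession differed from the others in 42551 of 58143 tested genes (73.2%).

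**Figure D1:**
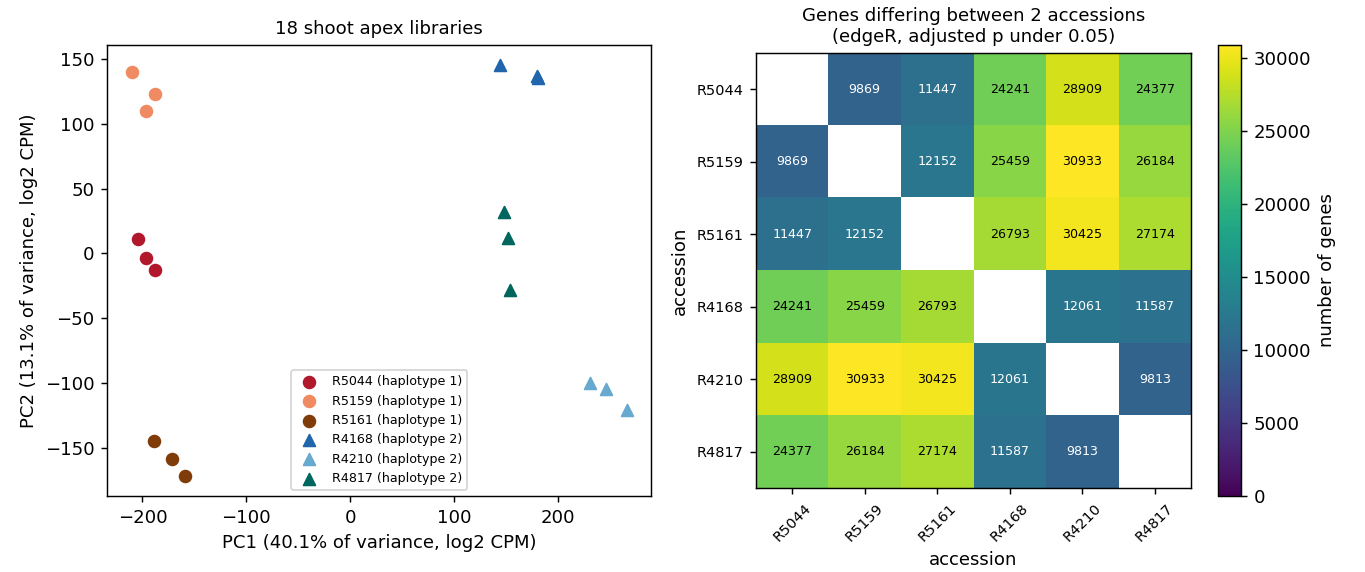
Left, the 18 libraries on the first 2 principal components of log2 CPM (axes in component units, with percent of variance), circles for haplotype 1 and triangles for haplotype 2. Right, the number of genes that differ between each pair of accessions (edgeR, adjusted p under 0.05), from 9813 within haplotype 2 to 30933 between haplotypes.

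A-subgenome transcripts took a larger share of the counts in haplotype 1 apices, mostly through chromosomes A02 and C02. Genes on A chromosomes held 48.4% ± 0.833 of the chromosome counts in haplotype 1 and 46.3% ± 0.912 in haplotype 2 (mean and SD, n = 3 accessions; exact permutation p = 0.1, the smallest possible). Without A02 and C02 the shares were 47.2% ± 0.997 and 46.4% ± 1.01 (exact permutation p = 0.3), with R4210 (47.6%) above R5159 (46.1%). In the accession-level edgeR test, 6.78% of tested A genes were higher in haplotype 1 against 5.94% of C genes, and 6.83% were lower against 8.59% of C genes. Fisher's exact tests over genes gave p of 5.17e-05 and 8.84e-15. Without A02 and C02 the excess of higher calls on A chromosomes was lost (6.17% against 6.23%, p = 0.81 by Fisher's exact test), while lower calls stayed less frequent there (6.91% against 7.96%, p = 7.72e-06). Genes with at least 10 counts numbered 48310 ± 845 per library in haplotype 1 and 49910 ± 77.7 in haplotype 2 (n = 3 accessions, exact permutation p = 0.1). The mean total per library was nevertheless higher in haplotype 1, with overlap between the haplotypes (exact permutation p = 0.2).

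Between the haplotypes, 7920 of 57827 tested genes (13.7%) differed against the spread between accessions, 3544 of them higher and 4376 lower in haplotype 1. A fold of at least 2 was reached by 2395 of the higher and 3924 of the lower genes. Against the smaller spread between libraries, the means of these 6 accessions differed in 36359 of 58143 genes (62.5%), with 17159 higher and 19200 lower. In 23460 genes (40.3%) all 3 accessions of one haplotype also lay beyond all 3 of the other, 10871 of them higher in haplotype 1. Whatever the p-value, the accession means did not overlap in 43.4% of genes, where chance gives 10% for 3 against 3. Of the 7920 genes, 7826 also passed the test of accession means with the same sign and 7816 were separated. The accession-level count was 20341 with DESeq2 on the same sums (9731 higher and 10610 lower), 15769 with limma-voom on the 18 libraries with accession as an estimated block, and 23809 with the 18 libraries as replicates. It fell with every accession left out. It was 2282 without R5044, 2130 without R5159, 2267 without R5161, 4591 without R4168, 310 without R4210 and 2547 without R4817, with 3 against 2 accessions in each.

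The strongest regional difference lay at the start of chromosome C02, where transcript levels were lower in all 3 haplotype 1 accessions, most in R5159 and R5044 and least in R5161. The bounds of this and the following segments were set after the data were seen. The 1058 gene models numbered 1 to 1000 summed to 1533 ± 1710 CPM in haplotype 1 and 12030 ± 539 CPM in haplotype 2 (mean and SD, n = 3 accessions), a ratio of 0.127. R5159 had 279 ± 47.9 CPM over this segment, R5044 had 833.8 ± 170 and R5161 had 3485 ± 43.4 (n = 3 libraries each), while R4168, R4210 and R4817 had 11770 ± 305, 12650 ± 404 and 11670 ± 424 CPM. The number of its genes at 1 CPM or more was 131.3 ± 92.7 in haplotype 1 and 479.1 ± 14.4 in haplotype 2. Both measures had an exact permutation p of 0.1, the smallest possible. Of 604 tested genes in the segment, 570 were lower and 7 higher in haplotype 1 in the test of accession means, and 237 were lower and 3 higher in the accession-level test. The median log2 fold change in the test of accession means was -6.6 relative to all genes. That fitted value averages the accessions on the log scale, and 130 of the 604 genes had no count in haplotype 1. With counts under 3 over the 9 libraries set to 3, the median of pooled CPM was -4.61. Without that floor, the accession-level test gave a median of -4.53 over its 572 tested genes. Pooling adds counts over the accessions, so R5161, the least low, weighs most in haplotype 1. The gap between -6.6 and -4.61 therefore does not measure the effect of genes at 0 alone.

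At the start of chromosome A02 the opposite direction was measured. The 867 gene models numbered 1 to 800 summed to 19220 ± 2220 CPM in haplotype 1 and 9811 ± 346 CPM in haplotype 2, a ratio of 1.96 (n = 3 accessions, exact permutation p = 0.1). The median log2 difference from the haplotype 2 mean was 0.87 in R5044, 1.16 in R5159 and 0.75 in R5161. Of 537 tested genes, 352 were higher and 75 lower in the test of accession means (166 and 15 in the accession-level test). The number of genes at 1 CPM or more differed little, at 427.5 ± 2.93 against 414.9 ± 5.54. The C02 and A02 segments together had 0.95 of the haplotype 2 CPM in haplotype 1, and the sources used here do not say how reads that match both copies of a gene were counted.

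**Figure D2:**
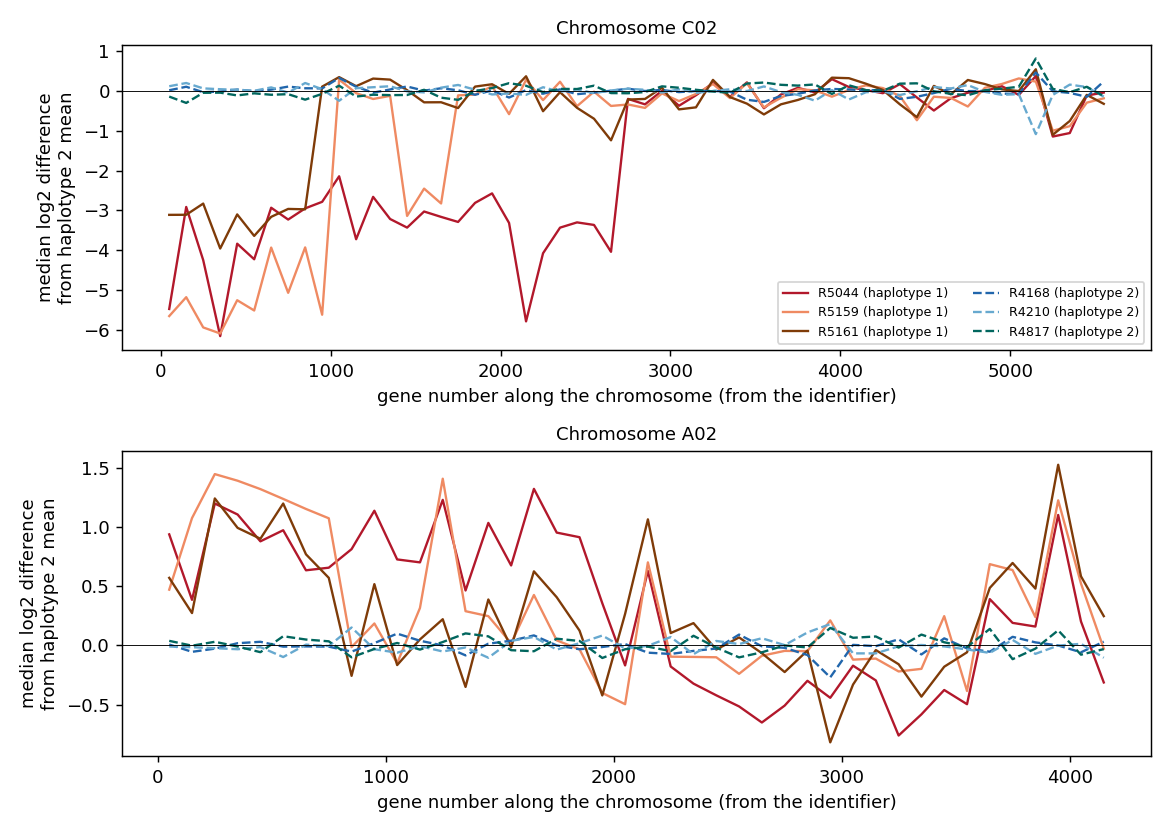
Median log2 difference of each accession from the haplotype 2 mean, log2(CPM + 0.1), in windows of 100 gene numbers along C02 (top) and A02 (bottom), solid lines for haplotype 1 and dashed lines for haplotype 2. That mean includes the haplotype 2 accession being drawn, which pulls the dashed lines toward 0. The haplotype 1 accessions lie below 0 at the start of C02 and above 0 at the start of A02, and R5044 keeps the difference on C02 up to gene 2700.

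The extent of both shifts differed among haplotype 1 accessions. On C02, genes 1101 to 2700 summed to 1843 ± 276 CPM in R5044, 10880 ± 265 in R5159 and 13360 ± 506 in R5161 (n = 3 libraries), against 14050 ± 606 over the haplotype 2 accessions. In the 17 windows of C02 that follow the first 10, up to gene 2700, the median was at least 1 log2 unit below the haplotype 2 mean in 17 windows in R5044, in 3 in R5159 and in 1 in R5161. On A02, R5044 was at least 0.4 log2 units above the haplotype 2 mean in all 11 windows from gene 801 to 1900, and R5159 and R5161 in 2 and 3 of them. For C02 genes 1101 to 2700, the median difference from the haplotype 2 mean on log2(CPM + 0.1) was -3.37 in R5044, -0.38 in R5159 and -0.13 in R5161. The median log2 fold change in the test of accession means was -2.47, and that of pooled CPM, with counts under 3 over the 9 libraries set to 3, was -0.77. Only 37 of its 851 tested genes were under that floor in haplotype 1, and pooling gives most weight to the accessions with the most counts.

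Chromosome by chromosome, C02 held the largest excess of genes lower in haplotype 1, and A02 the largest excess of higher genes, in both tests. In the accession-level test, 406 of 2815 tested C02 genes were lower (14.4% against 7.39% elsewhere, odds ratio 2.11, adjusted p = 8.08e-34 by Fisher's exact test) and 308 of 2368 A02 genes were higher (13% against 6.05%, odds ratio 2.32, adjusted p = 1.76e-32). Chromosome C03, which carries the LFY copy that defines the haplotypes, had 666 of 4617 genes past the threshold, 14.4% against 14.1% elsewhere (adjusted p = 0.625). Its calls were more often higher in haplotype 1 (7.49% against 6.24%, adjusted p = 0.00393). The region around the LFY copy was not analysed here.

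The start of C03 was higher in haplotype 1 on average, and the haplotype 2 accessions differed in how far a low segment reached. Against the median of the other 5 accessions, R4168 was lower over genes 1 to 400 (median log2 difference -3.09) and R4210 over genes 1 to 200 (-3.3). R4817 was lower there only over genes 401 to 500 (-0.555). Genes 1 to 500 summed to 6633 ± 567 CPM in haplotype 1 and 3626 ± 1630 CPM in haplotype 2 (n = 3 accessions, exact permutation p = 0.1). R4168 had 2051 ± 10.8 CPM, R4210 had 3528 ± 148 and R4817 had 5299 ± 227 (n = 3 libraries). Of 322 tested genes, 242 were higher and 21 lower in haplotype 1 in the test of accession means, and 23 were higher and 5 lower in the accession-level test. At the start of A03, genes 1 to 200 summed to 3119 ± 20.4 CPM in R4168 and 2728 ± 39.2 in R4210, against 1805 ± 233 in R4817 and 1926 ± 195 over the haplotype 1 accessions.

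Some other segments differed mainly in single accessions and gave calls in the test of accession means but few in the accession-level test. Genes 4901 to 5500 of C05 summed to 988.1 ± 24.4 CPM in R4210 (n = 3 libraries), while the other accessions had between 6348 ± 335 in R4168 and 9920 ± 150 in R5044. In this segment 305 of 378 tested genes were higher and 19 lower in haplotype 1 by the test of accession means, and 5 were higher and 6 lower by the accession-level test. Genes 4601 to 4800 of A05 summed to 628.5 ± 15.2 CPM in R5044 and 3768 ± 81.7 in R4210, with the other accessions between 1976 ± 49.1 and 2112 ± 13.6. The scan found 63 shifted segments with 8126 genes, 40 of them only 1 window long. These held 14.2% of the tested chromosome genes, 13.6% of the accession-level calls and 16.4% of the calls in the test of accession means.

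**Figure D3:**
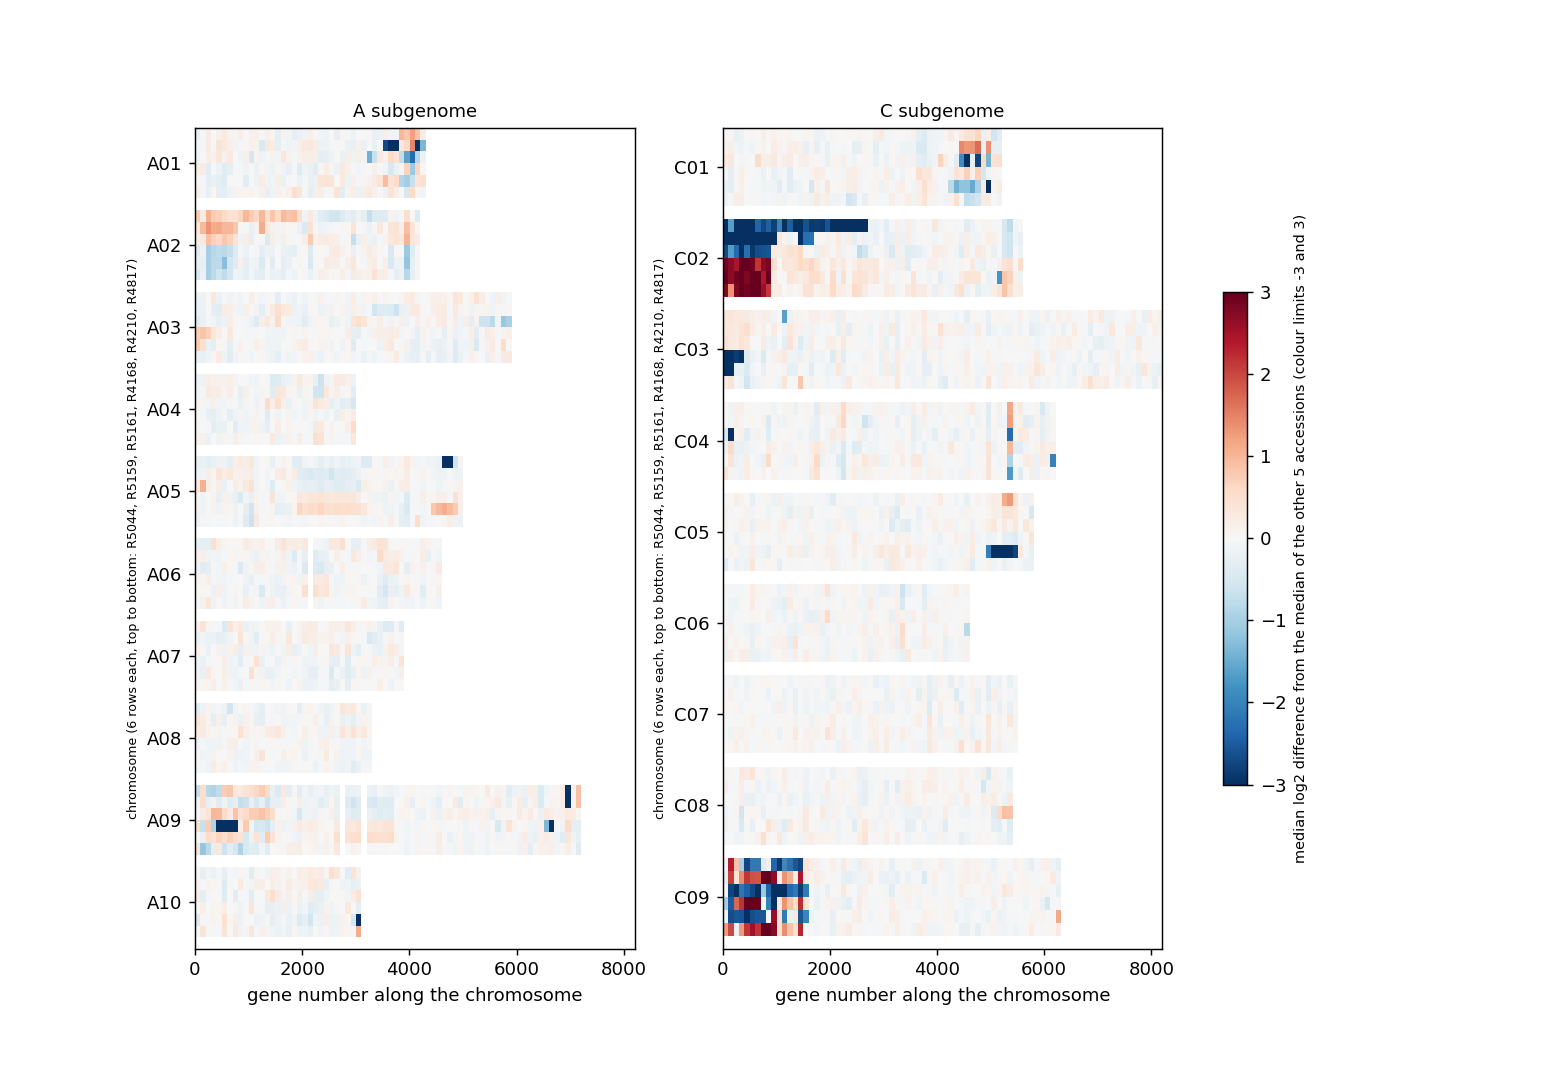
Median log2 difference of each accession from the median of the other 5, log2(CPM + 0.1), in windows of 100 gene numbers (x axis) along the 19 chromosomes (y axis, 6 accessions each), blue for lower and red for higher. The longest lower segment covers 27 windows of C02 in R5044.

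**Figure D4:**
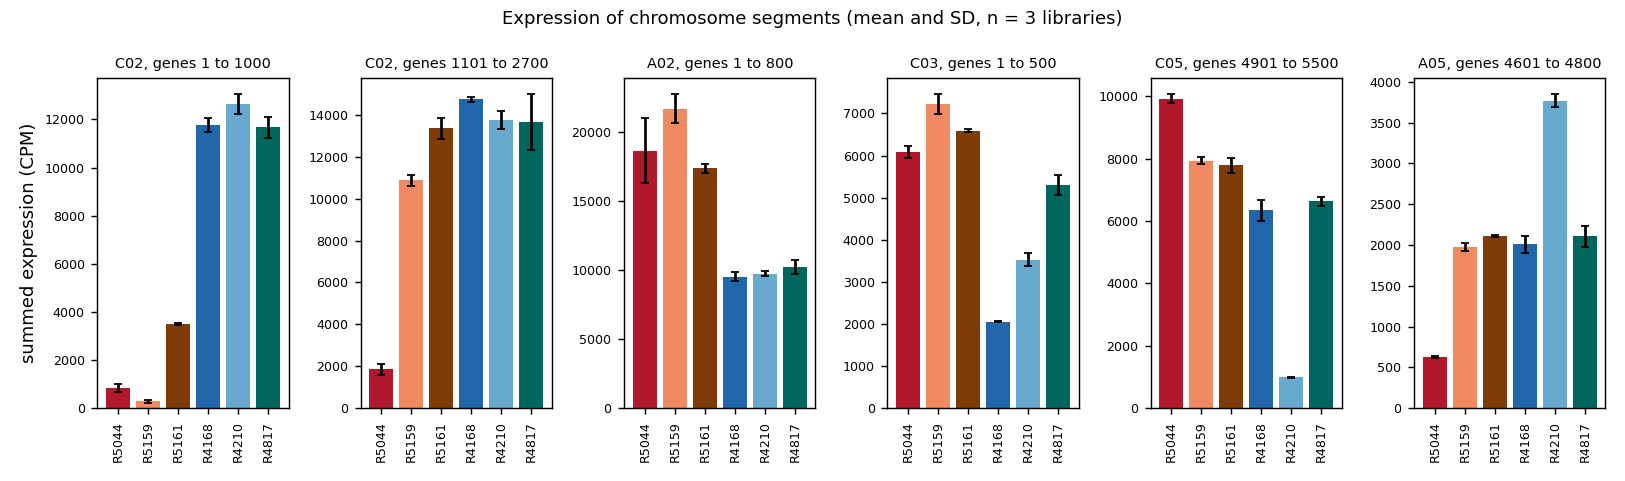
Summed CPM of the genes in 6 chromosome segments for each accession (bars, mean; error bars, SD; n = 3 libraries). C02 genes 1 to 1000 range from 279 CPM in R5159 to 12650 in R4210, and A02 genes 1 to 800 from 9513 in R4168 to 21680 in R5159.

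Genes called in one direction lay beside each other more often than shuffled calls. Of the calls in the test of accession means, 41.1% had a next tested neighbour called in the same direction, against 31.6% in shuffles (permutation p = 0.0001, the smallest that 10000 shuffles can give). The accession-level calls gave 14.6% against 7.11% (permutation p = 0.0001). With the genes of all shifted segments left out, the shares were 36.3% against 30.7% and 12.2% against 7.15%, both with the same p. The table has 6314 gene models with a dot suffix, which were read under the gene number before it and kept as separate genes. Neighbours can therefore share a gene number, and the shuffles were not run without these models.

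Some genes were expressed in every library of one haplotype and all but absent from the other. At 1 CPM or more in each of 9 libraries and at most 3 counts over the 9 of the other haplotype, 110 genes were found with haplotype 2 expression and 30 with haplotype 1 expression. Of the 110 genes, 97 lay on the C subgenome and 68 on C02 alone, and 67 were in the shifted segments already described. Of the 30 genes, 20 lay on the C subgenome and 3 on C02, and 8 were in shifted segments. On C03 there were 4 such genes with haplotype 2 expression and 3 with haplotype 1 expression. Fisher tests were not run on these counts.

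By the rule for named genes, the highest fold changes in the accession-level edgeR test belonged to BnaA03T0464300ZS and BnaC08T0216200ZS. BnaA03T0464300ZS had 61.1 ± 52.6 CPM in haplotype 1 (mean and SD, n = 3 accessions) and 0 counts in haplotype 2, at least 5030-fold higher against 3 counts over the group (edgeR adjusted p = 0.0201). This bound and those that follow compare counts pooled over the libraries of a haplotype, not the printed means of accessions. BnaC08T0216200ZS had 52.2 ± 7.58 CPM and 0 counts, at least 4170-fold higher (edgeR adjusted p = 0.00836). The lowest were BnaC03T0306900ZS, with 0 counts in haplotype 1 and 132 ± 115 CPM in haplotype 2, at least 13300-fold lower (edgeR adjusted p = 0.0199), and BnaC06T0284600ZS, with 0 counts and 46.4 ± 43.9 CPM, at least 4240-fold lower (edgeR adjusted p = 0.0441). The fitted log2 fold changes were 15.44 and 15.2 for the higher genes. They were -16.48 and -14.98 for the lower genes, and all 4 depend on the prior count because one group is at 0. For the same reason no SE is given for them. With 1 accession left out, BnaC08T0216200ZS passed in all 6 cases. BnaA03T0464300ZS missed the threshold without R5161 (edgeR adjusted p = 0.0601) and without R4210 (0.063), BnaC03T0306900ZS without R4168 (0.0507) and without R4210 (0.0576), and BnaC06T0284600ZS without every accession except R4168 (0.084 without R5044, 0.0885 without R5159, 0.0878 without R5161, 0.128 without R4210 and 0.0985 without R4817). BnaC03T0306900ZS also missed it with limma-voom (limma adjusted p = 0.05) and with limma-voom and accession as an estimated block (0.178), and BnaC06T0284600ZS with limma-voom (0.247).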

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

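The alternatives were fixed before the data were examined, except thinning, leaving out segment genes, leaving out R4817 replicate 1 or 2, leaving out A02 and C02, and all settings of the C02 and A02 segments. The accession-level count of 7920 stayed within 1.5 times in 10 of 20 alternatives, among them 7308 without R4817 replicate 1 and 7715 without R4817 replicate 2. It was higher with DESeq2 (20341), with 9 against 9 libraries as replicates (23809) and with limma-voom and accession as an estimated block (15769, consensus correlation 0.49), and fell to between 310 and 4591 with 1 accession left out, where 3 stand against 2. Without R4210 it was 310, with 84 higher and 226 lower. The cause of the DESeq2 count was not tested. The test of accession means stayed within 1.5 times of 36359 in 32 of 33 alternatives, with 35356 to 37492 when 1 library and 32637 to 36236 when 1 accession was left out. A minimum 2-fold change left 20407 genes. Separated genes fell to 8643 when all 9 libraries of one haplotype had to lie beyond all 9 of the other, a stricter rule by construction. The count of any difference among accessions ranged from 34629 to 43937 in 4 alternatives, and the C02 and A02 medians kept their sign in all 9 (-7.45 to -4.53 and 0.889 to 1.1). Their repeated comparison with random gene sets adds no support, because the segments were chosen by such a comparison in the same data. Of the named genes, BnaC08T0216200ZS passed in 19 of 19 alternatives and BnaA03T0464300ZS in 17 of 19 (edgeR adjusted p up to 0.063). BnaC03T0306900ZS passed in 15 of 19 (limma adjusted p up to 0.178, with accession as an estimated block). BnaC06T0284600ZS passed in 10 of 16 (limma adjusted p up to 0.247, with limma-voom). It did not pass the low-count filter of the fits with 9 against 9 libraries or with accession as an estimated block. Without A02 and C02, the haplotype difference in the A share of counts moved from 2.14 to 0.748 percentage points. The A minus C difference in higher calls was lost, from 0.842 to -0.0526 percentage points (p = 0.81 by Fisher's exact test). Both differences thus rest largely on these 2 chromosomes.

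Libraries share replicate numbers across accessions, but these did not pair them: deviations of same-numbered libraries correlated at -0.15 to 0.21, and 7 of 18 libraries correlated best with their own number. With a replicate block the 9 against 9 comparison gave 23015 genes and the test of accession means 35963. The alternatives for LFY copies, for gene lists and for calls within 100 kb were not run.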

Other observations

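Further segments set single accessions apart, in windows chosen after the data were seen. Genes 3501 to 3800 of A01 summed to 173.7 ± 12.4 CPM in R5159 (mean and SD, n = 3 libraries), while the other accessions had between 2717 ± 38.2 in R4168 and 4914 ± 44.3 in R5161. Genes 301 to 800 of A09 summed to 1901 ± 303 CPM in R4168 and to between 4938 ± 495 in R4817 and 9404 ± 263 in R5161 elsewhere. Genes 6901 to 7000 of A09 were at 55.56 ± 3.68 CPM in R5044 and 55.19 ± 2.34 in R5159, and at 822.9 ± 19.4 or more in the other accessions.

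The start of C09 differed among accessions within both haplotypes. Genes 201 to 700 summed to 626.3 ± 36.4 CPM in R4210, 676.9 ± 25.7 in R5161 and 2034 ± 537 in R5044, against 6399 ± 635 in R4817, 6756 ± 354 in R5159 and 15780 ± 2460 in R4168. Genes 901 to 1500 were low in R5044 (1059 ± 28.8 CPM) and R5161 (913.7 ± 8.48 CPM), and the other accessions had 5083 ± 292 to 6178 ± 176. The haplotype means of these 2 segments had exact permutation p of 0.7 and 0.3.

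Of the tests below, the A02 rise, the accession permutations and the share of calls in segments were chosen after the results were seen, and the segments and thinning were added after the data were seen. The first pattern is the low start of C02 with the high start of A02 in the 3 haplotype 1 accessions. A depth difference is argued against, since the C02 median was -6.47 after thinning to 21960992 counts per library. Plain loss of reads from diverged C02 copies is argued against as the whole account, since it predicts no A02 rise and the lowest median rise was 0.752 (log2) in 3 of 3 haplotype 1 accessions. A replacement of C02 sequence by A02 sequence (homoeologous exchange) is consistent with the combined CPM of both segments, at 0.95 of haplotype 2. Assignment of C02 reads to A02 predicts the same 0.95 and cannot be told apart from replacement without reads or DNA, so the pattern stays a hypothesis.

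The second pattern is that accessions with low windows on a chromosome often had high windows on the same-numbered chromosome of the other subgenome, where windows need not adjoin and positions were not matched. Of 31 accession and chromosome combinations with at least 2 low windows, 22 had at least 2 high windows on the partner. In 10000 permutations of the accessions the average was 15.5 (one-sided permutation p = 0.0008). Low and high were set against the median of the other accessions, so a shift shared by a haplotype can be counted in both haplotypes. R5044, R5159 and R5161 entered with C02 low and A02 high, and R4168, R4210 and R4817 with the reverse. On chromosome number 9, R5044 and R4168 entered in both directions. The combinations are therefore not independent. Without chromosome number 2 the count was 16, against 12 (one-sided permutation p = 0.0068). Counting only segments of at least 2 adjoining windows, 17 of 27 had a partner, against 10.3 (one-sided permutation p = 0.0011), and without A02 and C02 11 of 20, against 6.87 (one-sided permutation p = 0.0054). Homoeologous exchange in single accessions may account for part of these, and R4210 (C05 low, A05 high) and R5044 (A05 low, C05 high) are examples in opposite directions. Assignment of reads to the other copy was not tested here and stays open, as does whether the partners are homoeologous positions.

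The third pattern is the breadth of the haplotype difference. A depth difference and the shifted segments are argued against as its cause, since the accession-level count was 8147 after thinning, against 7920, and the segments held 13.6% of the accession-level calls on chromosomes, with 14.2% of the tested genes. Only 1 of the 10 splits of the 6 accessions, the real one, gave as many genes in the accession-level test (7920, highest other 1), the test of accession means (36359, highest other 22899) and the separated genes (23460, highest other 3454), and 10 splits are too few for a share under 0.05. For any difference among accessions, 1 of 30 splits of the 18 libraries, the real one, gave as many genes (42551, highest other 713). That share is the smallest that 30 splits can give. It bears on differences among accessions and not on the haplotypes. The BnaC3.LFY haplotype, other genetic differences between the 2 sets of accessions and a difference in developmental stage at sampling stay open and were not tested. Loss of reads from diverged gene copies was not tested for this pattern either.

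Among the 9 libraries of each haplotype, 16 sets of values (totals, detected genes, shares of counts, the first principal component and segment sums) were searched for a library at the edge of its haplotype, and 0 were found. That search pools 3 accessions and does not test libraries within an accession. Within accessions, replicates 1 and 2 of R4817 had a Spearman correlation of 0.904 and a chi-square per degree of freedom of 55, the lowest and highest of the 18 pairs. On the second component R4817 replicates 1, 2 and 3 lay at 31.89, -28.07 and 11.67, and on the third at 91.51, 148.3 and 121.2.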
